A study of Mus musculus with 8 samples.

How the data were processed

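The series holds 8 RNA sequencing libraries of 3T3-L1 cells, 1 for each of 4 conditions (control with empty shRNA vector, shMaf1, shBrf1, ML-60218) at day 0 and day 2 of differentiation. Per the submitters' processing notes, poly(A) RNA libraries were aligned with STAR 2.4 to the mouse genome build mm10. The authors deposited 6 comparison tables, each of 1 perturbed library against the control library of the same day, over 31252 genes. In these tables the authors give expected counts (estimated counts) of read pairs per gene, rounded to whole numbers and not normalised, in columns named as means although each holds 1 library. The authors' log2 fold change compares the same pair of libraries after a normalisation that the tables do not describe. The p-value column of each of the authors' deposited tables was checked against an exact test with counting noise only. The test came within 0.01 for 93.58% to 99.22% of the genes with a count in either library of the table. The adjusted p-value column was not recomputed. The explanation sheet describes a test on replicates, which 1 library per group cannot give, so the deposited p-values were not used.

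The deposited quality tables give, per the file headers, percent of reads on ribosomal RNA, percent of ambiguous reads and percent of duplicate reads by their first 35 bases. They also give a score for 3′ bias of coverage (0 means no bias) and estimated reads in 3′ and 5′ untranslated regions, whose ratio was taken, per the file headers, the count of ERCC spike-in reads per the file headers, and other deposited numbers such as genes detected. The spike-in reads were divided by the aligned reads of the library. Columns of these tables that no comparison needed were left out.

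Counts of all 8 libraries were scaled together with TMM in edgeR 4.0.16 under R 4.3.3 and expressed as CPM. The log2 ratio of a gene was taken between CPM values after adding a pseudocount of 0.5. With 1 library per group there was no test across conditions: a gene was counted as higher or lower when the log2 ratio was at least 1 in size and the higher value was at least 1 CPM. Each named gene has an exact conditional binomial (Clopper-Pearson) 95% interval of its fold difference from the counts and library sizes. Where a gene had 0 counts in 1 library, its fold is given as a bound against a floor of 3 counts. The reads carry no molecular identifiers, so intervals and floors cover counting error only, and not variation between cultures. Computation outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

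The comparisons were each perturbation against control at each day, day 2 against day 0 in each condition, the difference of that response between each perturbation and control, and the likeness of the 3 perturbations at each day, which was set beside 100 simulated sets of unchanged libraries that share the control. For the last, the correlation runs across 12137 genes at a mean of 1 CPM or more. A total of 36 gene lists were fixed from textbook knowledge. For each list the median log2 ratio was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list was called apart at or below percentile 2.5 or at or above 97.5. Members below a mean of 1 CPM over the 8 libraries were left out. Of the lists, 31 were tested in 13 comparisons, 226 of 403 list results were apart, 3 lists had no measured member (endothelial and epithelial markers and mitochondrially encoded mRNAs), and 2 had fewer than 3 (skeletal muscle markers, and RNA polymerase III transcripts, of which Rmrp and Rpph1 were measured with a median log2 ratio of 5.07 in shBrf1 against control at day 2).

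Genes were named by a rule: Maf1, Brf1, Pparg, Cebpa, Cebpb, Fabp4, Dlk1 and Wnt6 in each comparison, then the 8 highest and 8 lowest log2 ratios past the size rule among genes that reach 5 CPM in either library, leaving out predicted and unnamed genes, then up to 4 of the most extreme members of each list that was apart. The text gives a selection of these, and the results of some genes are not reported here. The lists, the size rule, the naming rule and the alternatives were chosen before the data were examined, except the removal of a trend on transcript length, which was chosen after the quality tables had been seen.

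The alternatives were DESeq2 1.42.0 size factors, library totals only, ERCC spike-in scaling, pseudocounts of 1 and 0.1, no floor and a floor of 5 CPM, the authors' deposited log2 fold change for the comparisons against control, all expressed genes as the background of the lists, list members at 5 CPM or more, Spearman correlation, a mean of 10 CPM or more for likeness, and the removal of a trend of the log2 ratio on transcript length (lowess fraction 0.3; 96.1% of the 12137 genes had a length). Spike-in scaling supposes that equal amounts were added per unit of RNA in every library, which the labels do not state. List medians with members at 0 counts were also computed with these members at their bound, which moved 1 median by 0.41 and the other 24 by less.

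The calculation was tested on simulated data in each comparison of 2 libraries. Of 100 genes given a log2 difference of 1.5, 98%, 99%, 96%, 97%, 95% and 99% were recovered past the size rule in shMaf1, shBrf1 and ML-60218 against control, day 0 before day 2 for each, and 96%, 98%, 99% and 99% in day 2 against day 0 of control, shMaf1, shBrf1 and ML-60218. At a log2 difference of 3 the share was 100% in all of them. The exact intervals held the true fold for 93.5% to 96% of 200 genes, at most 1 of 31052 unchanged genes passed the size rule, and at most 3.4% of 29 unchanged lists were called apart. The 31052 genes included those below 1 CPM, which the floor leaves little room to pass. The simulated counts held counting noise only, without variation between cultures or shared regulation of list members. These shares are therefore not rates of false calls for the real libraries or lists.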

Results

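Messenger RNA was profiled by RNA sequencing in 3T3-L1 cells, a mouse fibroblast line that turns into adipocytes when given a hormone cocktail. The cells carried an empty shRNA vector (control), an shRNA against Maf1 (shMaf1) or an shRNA against Brf1 (shBrf1), or were treated with ML-60218, an inhibitor of RNA polymerase III. Maf1 encodes a repressor of RNA polymerase III, and Brf1 encodes a subunit of the initiation factor TFIIIB that this polymerase needs at tRNA genes. Each condition was sampled at day 0, before induction, and at day 2, after 2 days in a cocktail of ascorbic acid (25 µg/mL), IBMX (0.5 mM), which raises cAMP, the glucocorticoid dexamethasone (2 µM) and insulin (10 µg/mL). Every one of the 8 groups held 1 library, so no difference reported here has a replicate check. All comparisons against control on a day share its 1 control library, and whatever sets that library apart enters each of them. Intervals in parentheses are 95% counting intervals of a fold difference, and gene lists are described by their place among 10000 random lists of genes with matched expression. The labels did not state whether the ML-60218 cells carried the empty vector, which dose and vehicle were used, or when treatment began.

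Total counts per library were 31641883 and 30791487 in control at day 0 and day 2, 30292041 and 30041275 in shMaf1, 31759559 and 29035505 in shBrf1, and 30741021 and 29207262 in ML-60218. Ribosomal RNA took 7.8% of the reads in shBrf1 at day 2 and between 0.46% and 0.93% in the other 7 libraries. The 3′ bias score of coverage was 0.36 in shBrf1 and 0.22 in ML-60218 at day 2, against 0.15 in control and 0.08 in shMaf1 at day 2. ERCC spike-in reads made up 8.14 per 1000 aligned reads in shBrf1 and 7.76 in ML-60218 at day 2, against 5.46 in control and 4.98 in shMaf1. Between 44.35% and 49.98% of reads per library could be assigned to more than 1 gene or isoform, so values of close paralogs and overlapping genes are less certain.

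**Figure D1:**
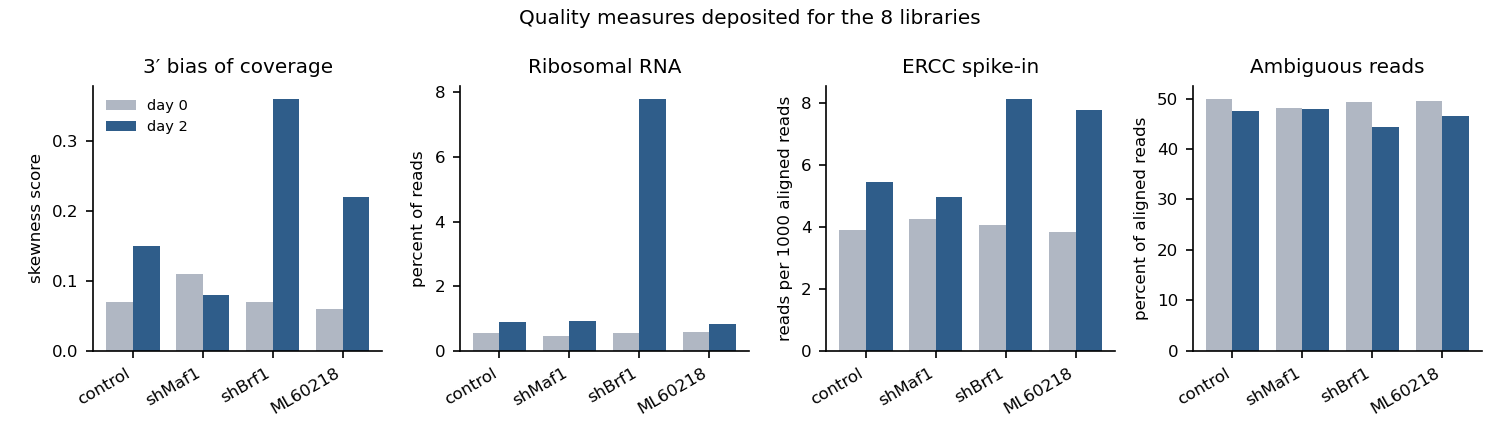
Quality measures of the 8 libraries, 1 bar per library, grey for day 0 and blue for day 2: 3′ bias score of coverage, percent of reads on ribosomal RNA, ERCC spike-in reads per 1000 aligned reads, and percent of ambiguous reads. The shBrf1 day 2 library had 7.8% ribosomal RNA reads, a 3′ bias score of 0.36 and 8.14 spike-in reads per 1000, and the ML-60218 day 2 library had 0.84%, 0.22 and 7.76.

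The mRNA of each shRNA target was lower in its knockdown. Maf1 (mm10 chromosome 15, 76351294 to 76354378) was 4.26-fold lower (3.83 to 4.75) in shMaf1 than in control at day 0, at 13.1 against 55.8 CPM, and 5.00-fold lower (4.45 to 5.62) at day 2, at 12.0 against 59.8 CPM. Brf1 (chromosome 12, 112959862 to 113000621) was 1.73-fold lower (1.57 to 1.91) in shBrf1 at day 0, at 19.0 against 32.9 CPM, which is short of the size rule of 2-fold, and 2.06-fold lower (1.82 to 2.35) at day 2, at 13.4 against 27.8 CPM. At day 2, Maf1 was 1.09-fold lower (1.01 to 1.17) in shBrf1. Brf1 was 1.098-fold lower (0.9931 to 1.214) in shMaf1, at 25.3 against 27.8 CPM, with an interval that includes 1-fold. These folds are alike in size and the intervals cover counting error only, so they do not set the genes apart. At day 0, Brf1 was 1.098-fold lower (1.007 to 1.198) in shMaf1 and Maf1 was 1.093-fold higher (1.026 to 1.164) in shBrf1. With ML-60218 neither gene differed detectably at day 2, at 61.8 against 59.8 CPM for Maf1 and 25.5 against 27.8 CPM for Brf1. CPM denotes counts scaled by library total and TMM factor. With 1 library per condition and day, other differences between a knockdown line and control cannot be told apart from the knockdown. Neighbouring genes on chromosome 10, described below, differed from control in both knockdowns but not with ML-60218.

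**Figure D2:**
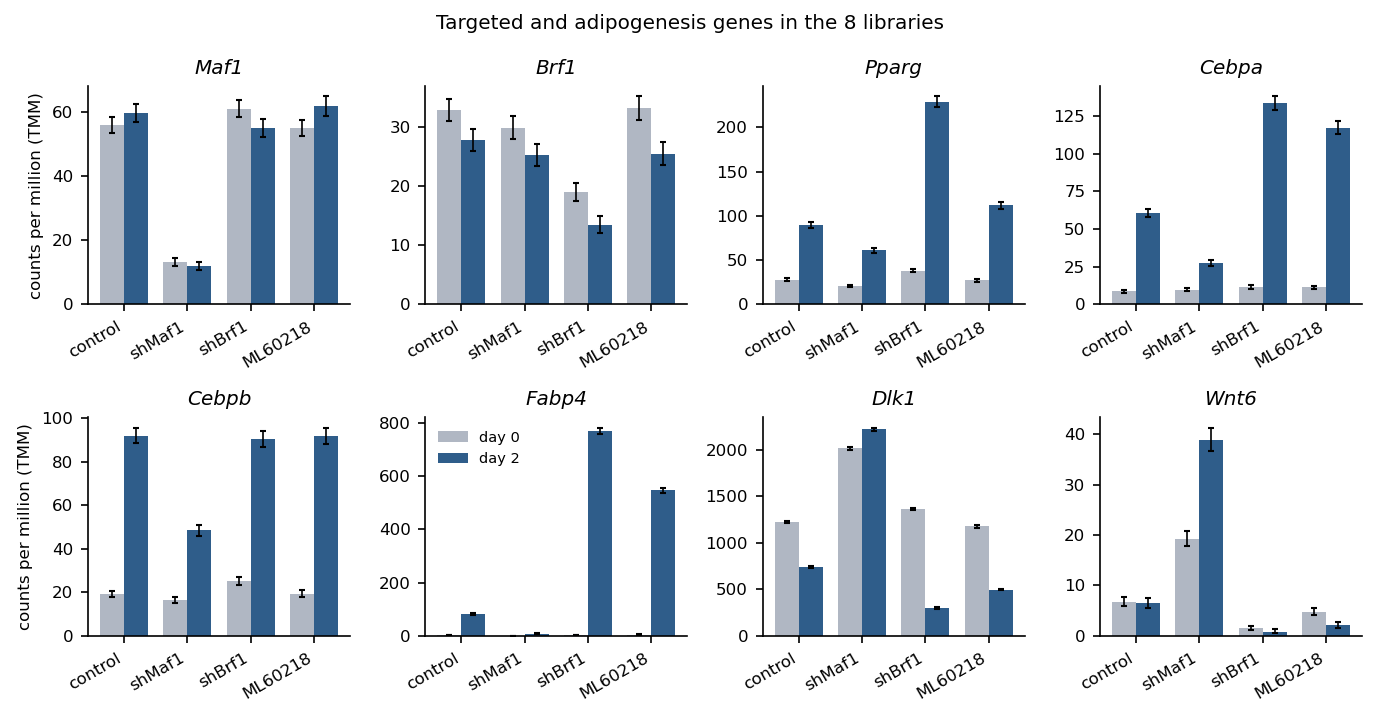
Abundance in CPM (bars, with 95% counting intervals) of Maf1, Brf1, Pparg (chromosome 6, 115361221 to 115490401), Cebpa (7, 35119293 to 35121931), Cebpb (2, 167688915 to 167690432), Fabp4 (3, 10204343 to 10208576), Dlk1 (12, 109452823 to 109463336) and Wnt6 (1, 74771892 to 74785319) in the 4 conditions, grey for day 0 and blue for day 2. Fabp4 at day 2 stood at 8.02 CPM in shMaf1, 81.1 in control, 546 in ML-60218 and 769 in shBrf1.

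Day 2 against day 0 in control cells addressed the response to the differentiation cocktail. Genes of the adipocyte programme were higher at day 2: Fabp4, a fatty acid carrier of adipocytes, was 25.1-fold higher (20.8 to 30.6), at 81.1 against 3.23 CPM, Adipoq, which encodes the hormone adiponectin, was 25.3-fold higher (17.2 to 38.7), and Cidec, a lipid droplet protein, was 52.9-fold higher (32.8 to 91.2). Pparg and Cebpa, the central transcription factors of adipogenesis, were 3.19-fold higher (2.97 to 3.44) and 6.91-fold higher (6.11 to 7.83), and Cebpb, an early factor of the same cascade, was 4.78-fold higher (4.39 to 5.21). Dlk1, a preadipocyte marker that restrains differentiation, was 1.65-fold lower (1.62 to 1.67). Genes induced by type I interferon were lower, with Ifit3 82.7-fold lower (70.8 to 97.3), at 5.39 against 446 CPM, and Usp18 17.7-fold lower (15.0 to 21.1).

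Ordered by the log2 ratio, which adds 0.5 CPM to each value, the highest genes were Prg4, a lubricating glycoprotein, 1468-fold higher (629 to 4523), Hp, which encodes haptoglobin, 516-fold higher (295 to 1000), Pip, which had no count at day 0 and was at least 1117-fold higher, and Lcn2, a lipocalin, 359-fold higher (221 to 628). The 19 measured adipocyte lipid droplet and adipokine genes had a median log2 ratio of 2.56 (percentile 100), with 16 members higher past the size rule and 0 lower, and the 18 glucocorticoid receptor targets had 2.62 (percentile 100, 13 higher, 1 lower), among them Fkbp5 at 11.8-fold (11.2 to 12.5) and Glul at 22.6-fold (20.9 to 24.4). Cell cycle genes of S and G2/M phase had a median of 1.73 (percentile 100), with 32 of 35 higher, such as Top2a, 8.59-fold higher (8.26 to 8.94). cAMP and CREB targets had 0.96 (percentile 100, 6 higher, 3 lower of 14), including the phosphodiesterase Pde4b, 8.01-fold higher (7.34 to 8.76). Cholesterol synthesis genes had 0.84 (percentile 100, 9 of 20 higher) and ribosome biogenesis genes 0.89 (percentile 100, 10 of 25 higher), among which Myc was 4.30-fold higher (3.93 to 4.71). Fatty acid and triglyceride synthesis genes had a median of 0.55 (percentile 99.73, 9 of 20 higher), which was -0.12 under spike-in scaling. NF-kB and inflammatory genes had 0.66 (percentile 99.9, 5 higher, 1 lower of 17) and insulin and IGF signalling genes 0.63 (percentile 99.96, 6 higher, 2 lower of 18), which turned to -0.01 and -0.04 under spike-in scaling.

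The 26 interferon response genes had a median log2 ratio of -2.88 (percentile 0), with 23 lower and 0 higher. Preadipocyte markers and inhibitors of adipogenesis had -0.52 (percentile 0.03, 2 higher, 6 lower of 25), with Gata2 4.25-fold lower (3.62 to 5.01) and Ly6a 11.3-fold higher (10.8 to 11.7). Smooth muscle and myofibroblast markers had -1.51 (percentile 0.02, 4 of 8 lower), among them Acta2, which encodes smooth muscle actin, 7.17-fold lower (6.76 to 7.61). p53 targets had -0.43 (percentile 0.1) and immediate early genes -0.61 (percentile 0.53), although the latter median was 0.10 with members at 5 CPM or more and Fosl1 in that list was 11.4-fold higher (9.61 to 13.7). The list of replication-dependent histone genes, set up for mRNAs without poly(A) tails and called untailed histones below, had 2.29 (percentile 99.98, 4 of 5 higher). Whether its measured members, H2afx among them, lacked tails in these cells was not tested. As cell cycle genes were higher as well, these histones cannot be read as a sign of RNA quality alone. Bone and cartilage genes had 0.82 (percentile 97.76, 1 higher, 1 lower of 5). In all, 1119 genes were higher and 1212 lower past the size rule of 2-fold and 1 CPM, against 474 and 3609 under spike-in scaling and 830 and 1632 by library totals. Spike-in scaling shifted the median of all genes to -0.61 and library totals to -0.13, and the directions given here are relative to TMM scaling.

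**Figure D3:**
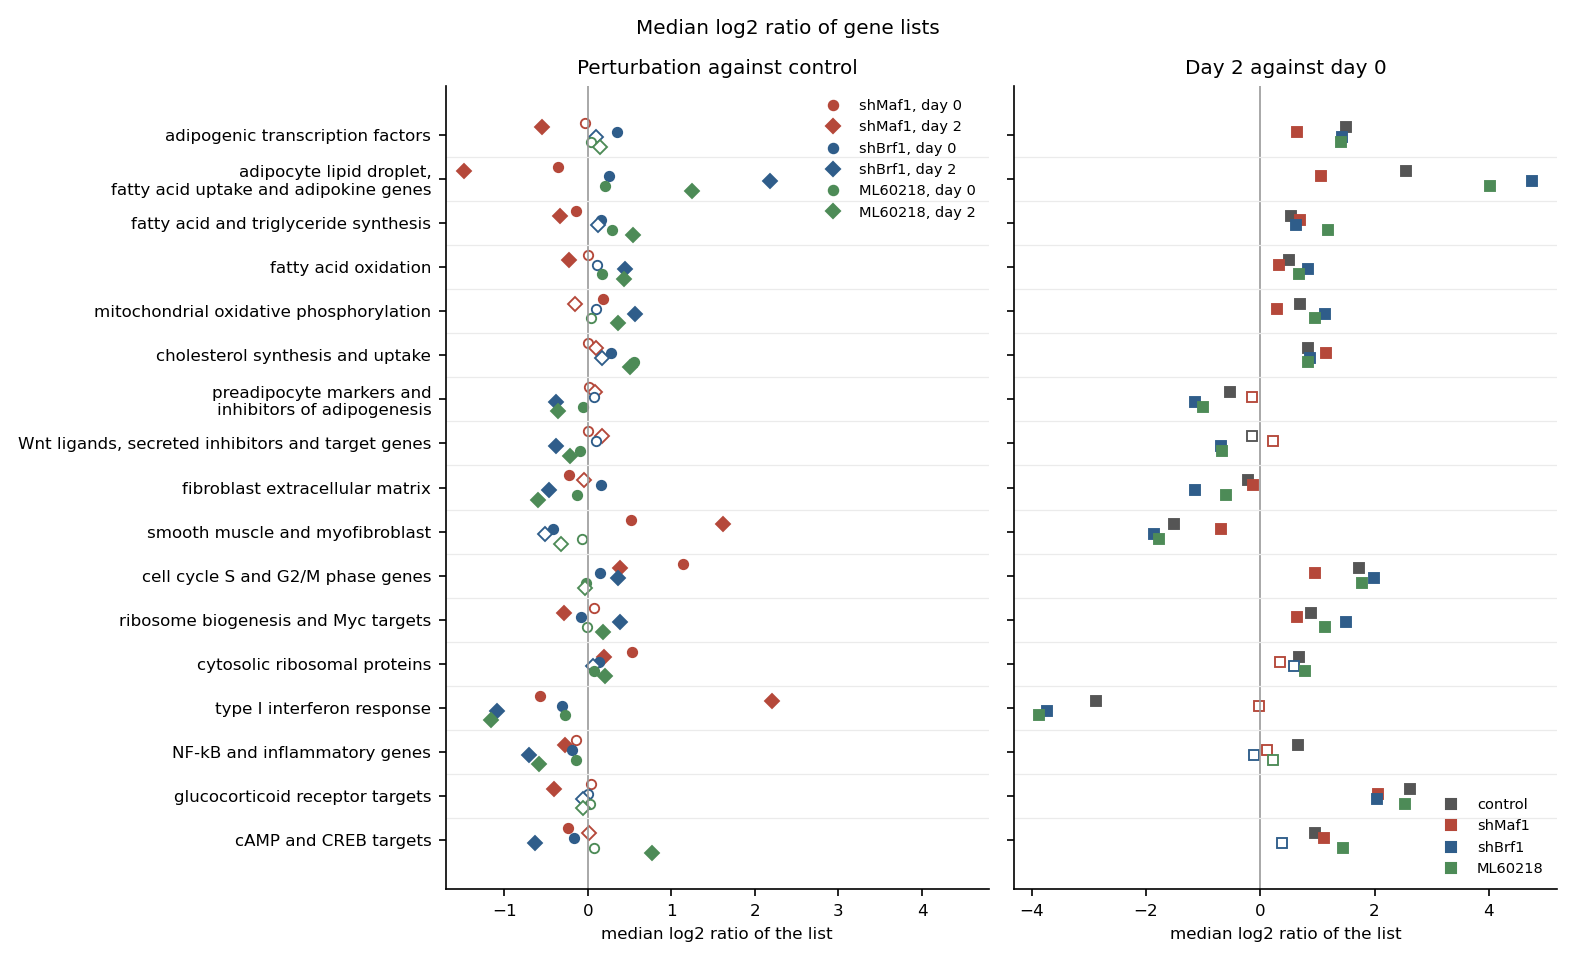
Median log2 ratio of the members of 17 gene lists. The left panel shows each perturbation against control (circles day 0, diamonds day 2) and the right panel day 2 against day 0 (squares) after TMM scaling, and filled symbols lie outside the central 95% of matched random lists. Adipocyte genes at day 2 had medians of -1.48 in shMaf1, 2.19 in shBrf1 and 1.24 in ML-60218, and interferon response genes 2.21, -1.09 and -1.16.

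shMaf1 against control at day 0 addressed how cells with Maf1 knockdown differed before induction. Cell cycle genes were higher in shMaf1: cyclins Ccnb1 and Ccnb2 were 3.00-fold higher (2.75 to 3.28) and 3.58-fold higher (3.17 to 4.06), and the ubiquitin-conjugating enzyme Ube2c was 3.32-fold higher (2.97 to 3.71). Fabp4 was 17.3-fold lower (7.70 to 48.1), at 0.187 against 3.23 CPM, and the fatty acid transporter Cd36 was 5.33-fold lower (2.49 to 13.1), both from low levels. Wnt6, a ligand that inhibits adipogenesis, was 2.83-fold higher (2.43 to 3.30) and Dlk1 was 1.65-fold higher (1.63 to 1.67), while Pparg was 1.36-fold lower (1.23 to 1.5) and Cebpa, at 9.81 against 8.77 CPM, was not detectably different. Pgm5 13.1-fold higher (10.2 to 16.9), Robo2 6.42-fold higher (5.50 to 7.54) and Tnmd 9.21-fold higher (6.37 to 13.7) were among the genes highest relative to control, and Thy1, a fibroblast surface marker, 3.76-fold lower (3.56 to 3.96), and the matrix protease Mmp3, 3.59-fold lower (3.05 to 4.26), among the lowest.

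Among the lists, 35 cell cycle genes had a median log2 ratio of 1.14 (percentile 100), with 22 higher and 0 lower. Cytosolic ribosomal protein genes had 0.52 (percentile 100) with none of 32 past the size rule, as in Rps6, 1.66-fold higher (1.63 to 1.68). The smooth muscle and myofibroblast markers had 0.51 (percentile 99.87, 2 of 8 higher). Endoplasmic reticulum chaperones had 0.15 (percentile 98.08, 0 of 20 past the size rule), which was -0.02 under spike-in scaling. Lower lists were the adipocyte genes at -0.35 (percentile 0, 3 of 19 lower), interferon response genes at -0.57 (percentile 0, 3 of 26 lower), with Ifit3 1.94-fold lower (1.89 to 2.00), basement membrane genes at -0.42 (percentile 0, 2 of 14 lower), with the collagen Col4a2 2.26-fold lower (2.21 to 2.31), and TGF-beta and BMP genes at -0.28 (percentile 0.09, 1 of 19 lower). Fibroblast matrix genes had -0.23 (percentile 0), although the proteoglycan Dcn was 2.56-fold higher (2.49 to 2.63). The RNA polymerase III subunits and factors were not apart from matched genes, at 0.02 (percentile 49.13). Past the size rule, 320 genes were higher and 125 lower, against 244 and 267 under spike-in scaling, which shifted the median of all genes to -0.16.

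At day 2, shMaf1 against control asked how cells with Maf1 knockdown differed early in differentiation. Adipocyte genes were lower in shMaf1: Fabp4 was 10.1-fold lower (8.85 to 11.6), at 8.02 against 81.1 CPM, Cidec 6.52-fold lower (5.37 to 7.99), and Lipe, which encodes hormone-sensitive lipase, 3.82-fold lower (3.58 to 4.08). Cebpa was 2.23-fold lower (2.05 to 2.42), Cebpb 1.90-fold lower (1.78 to 2.02) and Pparg 1.47-fold lower (1.38 to 1.56), and Dlk1 and Wnt6 were 2.99-fold higher (2.94 to 3.03) and 6.01-fold higher (5.15 to 7.04). Interferon-induced genes were higher, with Ifit3 12.5-fold higher (10.6 to 14.7), Irf7, a transcription factor of the interferon response, 9.29-fold higher (8.08 to 10.7), and Oasl2 7.42-fold higher (6.87 to 8.02). Nov, a secreted matricellular protein, was 56.8-fold higher (46.9 to 69.6), at 201 against 3.54 CPM, and Igf2, an insulin-like growth factor, 5.85-fold higher (5.61 to 6.11). The acute phase genes Saa3, 35.6-fold lower (21 to 65.6), and Hp, 12.2-fold lower (11.1 to 13.5), were among the lowest.

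The 19 adipocyte genes had a median log2 ratio of -1.48 (percentile 0), with 13 lower and 0 higher, and adipogenic transcription factors -0.55 (percentile 0, 1 higher, 5 lower of 19), where Srebf1, a regulator of lipid synthesis, was 2.22-fold lower (2.12 to 2.33) and Ebf1 2.17-fold higher (2.01 to 2.34). Fatty acid and triglyceride synthesis genes had -0.34 (percentile 0.05, 6 of 20 lower), with the glycerol-3-phosphate dehydrogenase Gpd1 6.57-fold lower (5.98 to 7.23). Glucocorticoid receptor targets had -0.40 (percentile 0.02, 3 higher, 4 lower of 18), as in the metallothionein Mt1, 3.56-fold lower (3.45 to 3.68), and in Hif3a, 3.90-fold higher (3.18 to 4.8). Interferon response genes had 2.21 (percentile 100, 23 of 26 higher). Smooth muscle and myofibroblast markers had 1.62 (percentile 100, 5 of 8 higher), including Acta2, 8.49-fold higher (8.01 to 9.01), and Myl9, 11.4-fold higher (9.54 to 13.7). Cell cycle genes had 0.38 (percentile 100) with none of 35 past the size rule, and ribosome biogenesis genes -0.29 (percentile 0.05), with Myc 1.92-fold lower (1.78 to 2.06). TGF-beta and BMP genes had -0.55 (percentile 0, 4 of 19 lower). Of the other lists set up as signs of RNA quality or of other cell types, 2 were lower too, the untailed histones at -0.66 (percentile 0.51, 1 of 5 lower) and bone and cartilage genes at -0.755 (percentile 0.47, 2 of 5 lower), as in Alpl, 3.27-fold lower (2.46 to 4.40). Past the size rule, 559 genes were higher and 426 lower, against 718 and 288 under spike-in scaling, which shifted the median of all genes to 0.15. Counts of Serpina3 genes, Tgtp2 and Brms1, also among the most extreme, may depend on reads shared with paralogs or overlapping genes, which was not measured per gene.

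**Figure D4:**
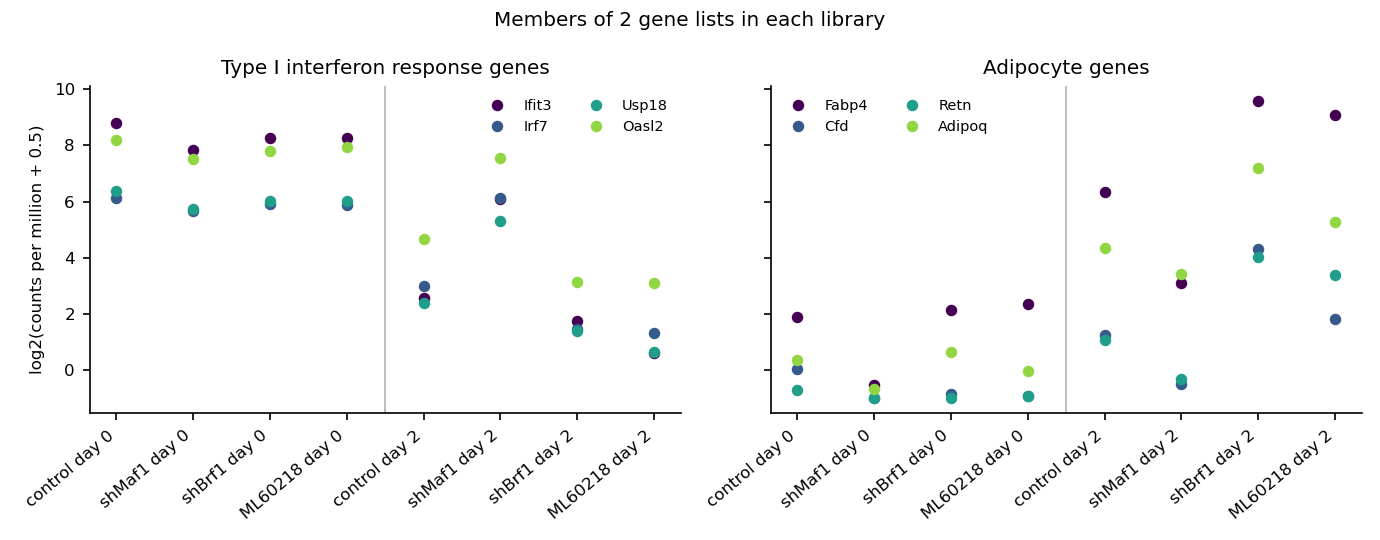
Log2 of CPM plus 0.5 of the interferon-induced genes Ifit3, Irf7, Usp18 and Oasl2 and the adipocyte genes Fabp4, Cfd, Retn and Adipoq in each of the 8 libraries. Ifit3 at day 2 stood at 67.2 CPM in shMaf1, 5.39 in control, 2.89 in shBrf1 and 1.03 in ML-60218, and Fabp4 at 8.02, 81.1, 769 and 546 CPM.

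shBrf1 against control at day 0 addressed how cells with Brf1 knockdown differed before induction, and fewer genes passed the size rule than in shMaf1. Cebpd, an early adipogenic transcription factor, was 2.00-fold higher (1.73 to 2.31), Pparg 1.36-fold higher (1.25 to 1.48), Cebpb 1.31-fold higher (1.19 to 1.46) and Cebpa 1.29-fold higher (1.11 to 1.51). Cd36 was 2.83-fold higher (2.01 to 4.06) and the lipid droplet protein Plin4 1.82-fold higher (1.74 to 1.90), while Cfd, of the same adipocyte list, was 8.63-fold lower (2.07 to 76.7), at 0.0602 against 0.519 CPM, and Fabp4, at 3.94 against 3.23 CPM, was not detectably different. Cfd had 18 counts in control at day 0 against 2 in shBrf1, 1 in ML-60218 and 0 in shMaf1. The shared control library may therefore underlie this value. Wnt6 was 4.44-fold lower (3.27 to 6.13), at 1.53 against 6.81 CPM. Pcolce2, a collagen processing enhancer, 5.09-fold higher (4.41 to 5.89), and Eln, which encodes elastin, 3.58-fold higher (3.07 to 4.19), were among the highest.

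Adipogenic transcription factors had a median log2 ratio of 0.35 (percentile 100) and adipocyte genes 0.25 (percentile 99.99, 1 of 19 higher), and cholesterol synthesis genes had 0.28 (percentile 100), as in Sqle, 1.46-fold higher (1.39 to 1.52). p53 targets had 0.18 (percentile 99.7), TGF-beta and BMP genes 0.26 (percentile 100, 1 of 19 higher) and fibroblast matrix genes 0.16 (percentile 99.93, 2 of 31 higher). Cytosolic ribosomal protein genes had 0.13 (percentile 97.82), which was -0.002 under spike-in scaling. Interferon response genes had -0.31 (percentile 0, 2 of 26 lower), with Mx1 2.19-fold lower (2.05 to 2.34), NF-kB and inflammatory genes -0.19 (percentile 0.07), immediate early genes -0.29 (percentile 0.01) and smooth muscle markers -0.42 (percentile 0.01). Untailed histones had 0.72 (percentile 100, 0 of 5 past the size rule) and the 3 measured macrophage markers 0.735 (percentile 99.76, 1 higher), of which Lyz2, 3.34-fold higher (2.89 to 3.87), lies among neighbouring genes on chromosome 10 that were mostly higher in shBrf1, and Cd68 was not detectably different at 1.38 against 0.866 CPM. The RNA polymerase III subunits and factors, at 0.05 (percentile 72.1), were not apart from matched genes. Past the size rule, 60 genes were higher and 61 lower, against 57 and 133 under spike-in scaling and 52 and 81 by library totals. Spike-in scaling shifted the median of all genes to -0.11.

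At day 2, shBrf1 against control asked how cells with Brf1 knockdown differed early in differentiation. Adipocyte genes were higher in shBrf1: Fabp4 was 9.48-fold higher (9.09 to 9.90), at 769 against 81.1 CPM, Adipoq 7.39-fold higher (6.77 to 8.07), Cfd, which encodes the adipokine adipsin, 10.6-fold higher (7.98 to 14.2), and Retn, which encodes resistin, 10.1-fold higher (7.45 to 13.9). Pparg was 2.56-fold higher (2.45 to 2.68) and Cebpa 2.20-fold higher (2.08 to 2.33), while Cebpb, at 90.5 against 92.0 CPM, was not detectably different. Dlk1 was 2.48-fold lower (2.42 to 2.55), Wnt6 7.63-fold lower (4.90 to 12.5) and Gata2, an inhibitor of adipogenesis, 4.13-fold lower (2.91 to 5.99). Among the lowest were the receptors Il1rl1, 8.53-fold lower (7.13 to 10.3), and Prokr1, 20.2-fold lower (12.1 to 36.5). In the same library, which had 7.8% ribosomal RNA reads, the ribosomal RNA precursor Rn45s was 25.2-fold higher (25.0 to 25.4) and the RNA polymerase III products Rmrp and Rpph1 were 152-fold higher (69.5 to 416) and 97.4-fold higher (41.4 to 302).

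The adipocyte list had a median log2 ratio of 2.19 (percentile 100), with 13 of 19 higher and 0 lower, in a library whose 3′ bias score was 0.36 against 0.15 in control. Mitochondrial oxidative phosphorylation genes had 0.57 (percentile 100, 1 of 29 higher) and fatty acid oxidation genes 0.45 (percentile 99.98, 1 of 20 higher), which were -0.11 and -0.15 under spike-in scaling. In these lists Cycs, which encodes cytochrome c, was 2.79-fold higher (2.70 to 2.88) and Acadm, a medium-chain acyl-CoA dehydrogenase, 3.04-fold higher (2.96 to 3.13). Ribosome biogenesis genes had 0.38 (percentile 99.96), cell cycle genes 0.36 (percentile 99.99), endoplasmic reticulum chaperones 0.32 (percentile 99.6) and tRNA synthetases and tRNA modification genes 0.21 (percentile 97.71), each with at most 1 member past the size rule, and under spike-in scaling these medians were -0.30, -0.31, -0.37 and -0.47. Dnajb9, an endoplasmic reticulum chaperone, was 3.56-fold higher (3.24 to 3.91). The untailed histone list had 0.91 (percentile 99.96, 1 of 5 higher), next to the higher cell cycle genes.

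Lower lists in shBrf1 at day 2 were the interferon response genes at -1.09 (percentile 0, 13 of 26 lower), with Oas2 9.10-fold lower (4.75 to 19.5), NF-kB and inflammatory genes at -0.70 (percentile 0, 7 of 17 lower), with the chemokine Cxcl5 3.29-fold lower (3.09 to 3.52), and fibroblast matrix genes at -0.47 (percentile 0, 1 higher, 7 lower of 31), with the thrombospondin Thbs1 4.96-fold lower (4.56 to 5.41) and tenascin C, Tnc, 4.5-fold lower (4.14 to 4.91). Preadipocyte markers had -0.38 (percentile 0.28, 4 of 25 lower), and Wnt ligands, inhibitors and targets -0.38 (percentile 0.52, 6 of 22 lower), with the Wnt antagonist Apcdd1 6.07-fold lower (4.93 to 7.54). cAMP and CREB targets had -0.63 (percentile 0.04, 3 of 14 lower). Past the size rule, 377 genes were higher and 667 lower, against 94 and 3016 under spike-in scaling and 283 and 832 by library totals. The shift of the median of all genes was -0.65 with spike-ins and -0.11 with library totals.

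ML-60218 against control at day 0 compared the 2 libraries before induction, and few genes differed. As the start of treatment and the vehicle were not stated, how long these cells had met the inhibitor, if at all, is not known. Angptl4, a secreted inhibitor of lipoprotein lipase, was 4.94-fold higher (4.72 to 5.17), at 323 against 65.4 CPM, Cd36 2.57-fold higher (1.81 to 3.70), and Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, 1.81-fold higher (1.75 to 1.89), while the adipocyte gene Cfd was 17.4-fold lower (2.74 to 723), at 0.0299 against 0.519 CPM. Cfd was lower than control in shMaf1 and shBrf1 at day 0 as well, so its value need not reflect ML-60218. Cholesterol synthesis enzymes were higher by less than the size rule, such as Lss, 1.61-fold higher (1.49 to 1.75), and Dhcr7, 1.56-fold higher (1.44 to 1.71). The transcription factor Spib was 2.85-fold lower (2.19 to 3.72), Dcn 2.02-fold lower (1.93 to 2.10) and the interferon-induced chemokine Cxcl10 2.05-fold lower (1.80 to 2.34).

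Cholesterol synthesis genes had a median log2 ratio of 0.56 (percentile 100, 0 of 20 past the size rule), fatty acid and triglyceride synthesis genes 0.29 (percentile 100, 0 of 20), adipocyte genes 0.20 (percentile 100, 2 of 19 higher) and fatty acid oxidation genes 0.17 (percentile 100, 0 of 20). Interferon response genes had -0.27 (percentile 0, 1 of 26 lower), NF-kB and inflammatory genes -0.15 (percentile 0), fibroblast matrix genes -0.13 (percentile 0, 1 of 31 lower) and endoplasmic reticulum chaperones -0.12 (percentile 0), as in Hspa5, 1.26-fold lower (1.24 to 1.28). The interferon list was lower than control in each perturbation at day 0, so the shared control library may enter these medians. The RNA polymerase III subunits and factors had 0.03 (percentile 64.98), not apart from matched genes. Past the size rule, 5 genes were higher and 9 lower, and these counts were 2 and 3 with a floor of 5 CPM and 11 and 16 under spike-in scaling. Angptl4, Cd36, Gm8898 and Gm14327 were among the 5, and the last 2 are named here after their values were seen.

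At day 2, ML-60218 against control asked how the inhibitor altered early differentiation. Adipocyte genes were higher with ML-60218: Cd36 was 11.5-fold higher (9.98 to 13.3), Fabp4 6.73-fold higher (6.45 to 7.03), at 546 against 81.1 CPM, Retn 6.31-fold higher (4.61 to 8.80) and Cidec 4.08-fold higher (3.76 to 4.42). Cebpa was 1.94-fold higher (1.83 to 2.05) and Pparg 1.25-fold higher (1.19 to 1.32), the latter with a log2 ratio of -0.28 under spike-in scaling, while Wnt6 and Dlk1 were 3.03-fold lower (2.24 to 4.16) and 1.49-fold lower (1.46 to 1.52). Dgat2 and Scd1, enzymes of triglyceride and monounsaturated fatty acid synthesis, were 3.66-fold higher (3.35 to 4.0) and 3.02-fold higher (2.96 to 3.09). Bnip3, a mitophagy receptor, 5.15-fold higher (4.86 to 5.46), and the carbonic anhydrase Car12, 15.2-fold higher (8.27 to 31.2), were among the highest. The matrix proteoglycan Ogn, 19.1-fold lower (13.7 to 27.3), and the chemokine Ccl2, 5.84-fold lower (4.98 to 6.89), were among the lowest.

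The adipocyte list had a median log2 ratio of 1.24 (percentile 100, 11 of 19 higher), in a library with a 3′ bias score of 0.22. Fatty acid and triglyceride synthesis genes had 0.54 (percentile 100, 6 of 20 higher), cholesterol synthesis genes 0.51 (percentile 100, 0 of 20), fatty acid oxidation genes 0.43 (percentile 100, 0 of 20) and oxidative phosphorylation genes 0.36 (percentile 100, 0 of 29), and under spike-in scaling these were -0.07, -0.10, -0.15 and -0.25. Likewise, endoplasmic reticulum chaperones had 0.38 (percentile 99.99, 1 of 20 higher), NRF2 antioxidant genes 0.39 (percentile 100), basement membrane genes 0.25 (percentile 98.89, 1 higher, 2 lower of 14) and cytosolic ribosomal proteins 0.21 (percentile 98.31), against -0.23, -0.22, -0.36 and -0.40 under spike-in scaling. cAMP and CREB targets had 0.76 (percentile 100, 3 higher, 2 lower of 14), with the coactivator Ppargc1a 4.48-fold higher (3.58 to 5.64) and Egr1 2.56-fold lower (2.24 to 2.93).

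Interferon response genes had a median of -1.16 in ML-60218 at day 2 (percentile 0, 16 of 26 lower), with Ifit3 5.24-fold lower (3.47 to 8.20), NF-kB and inflammatory genes -0.59 (percentile 0, 5 of 17 lower), fibroblast matrix genes -0.60 (percentile 0, 8 of 31 lower), with Lum 4.43-fold lower (4.16 to 4.73) and Dcn 3.27-fold lower (3.17 to 3.37), preadipocyte markers -0.35 (percentile 0.01, 3 of 25 lower), with Pdgfra 2.33-fold lower (2.29 to 2.37), and Wnt genes -0.21 (percentile 1.29, 3 of 22 lower). Past the size rule, 214 genes were higher and 375 lower, against 64 and 1495 under spike-in scaling, which shifted the median of all genes to -0.58.

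Day 2 against day 0 within each perturbed line addressed the differentiation response itself. In shMaf1, Fabp4 was 42.9-fold higher (19.4 to 118) at day 2, Adipoq 82.7-fold higher (31.9 to 305) and Cebpa 2.77-fold higher (2.43 to 3.17), while Dlk1 was 1.10-fold higher (1.09 to 1.11), with a log2 ratio of -0.20 under spike-in scaling, and Wnt6 2.02-fold higher (1.83 to 2.23). The adipocyte list had a median log2 ratio of 1.07 (percentile 100, 11 of 19 higher), or 1.48 with members at 0 counts set to their bound, glucocorticoid receptor targets had 2.06 (percentile 100, 13 of 18 higher) and cholesterol synthesis genes 1.15 (percentile 100, 14 of 20 higher). The interferon response genes were not apart, at -0.03 (percentile 33.3). Cell cycle genes had 0.95 (percentile 100, 13 of 35 higher), while oxidative phosphorylation and fatty acid oxidation genes had 0.29 (percentile 98.38) and 0.33 (percentile 99.09), which were -0.05 and -0.01 under spike-in scaling. Untailed histones had 1.77 in shMaf1, 2.41 in shBrf1 and 2.15 in ML-60218 (percentiles 100, 100 and 99.98). Counts past the size rule were 612 higher and 689 lower, against 351 and 1377 under spike-in scaling and 487 and 865 by library totals, and the spike-in shift of the median was -0.30.

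In shBrf1, Fabp4 was 195-fold higher (164 to 234) at day 2, Cidec 500.1-fold higher (286 to 968), Gpd1 428-fold higher (326 to 573), Pparg 6.01-fold higher (5.65 to 6.39) and Cebpa 11.8-fold higher (10.6 to 13.1), and Dlk1 was 4.57-fold lower (4.46 to 4.68). In ML-60218, Fabp4 was 118-fold higher (100.5 to 139), Cidec 354-fold higher (192 to 738), Pparg 4.14-fold higher (3.85 to 4.47) and Cebpa 10.4-fold higher (9.32 to 11.6), and Dlk1 was 2.36-fold lower (2.31 to 2.41). The adipocyte list had medians of 4.76 in shBrf1 and 4.02 in ML-60218 (percentile 100 in both, 16 and 17 of 19 higher), interferon response genes -3.74 and -3.88 (percentile 0, 22 and 23 of 26 lower), and preadipocyte markers -1.14 and -1.0 (percentile 0, 13 and 12 of 25 lower). Fibroblast matrix genes had -1.14 and -0.61 (percentile 0, 19 and 12 of 31 lower). Cell cycle genes had 1.98 and 1.77 (percentile 100, 32 and 27 of 35 higher). Oxidative phosphorylation genes had 1.13 and 0.96 (percentile 100, 18 and 13 of 29 higher), which were -0.08 and -0.33 under spike-in scaling. In shBrf1, 1835 genes were higher and 2158 lower, against 386 and 7283 under spike-in scaling and 1315 and 2762 by library totals, with shifts of the median of all genes of -1.18 and -0.23. In ML-60218, 1526 were higher and 1795 lower, against 326 and 7759 under spike-in scaling and 999 and 2553 by library totals, with shifts of -1.22 and -0.24.

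The difference between a perturbed line's day 0 to day 2 log2 ratio and that of control asked whether the response itself was altered. In shMaf1, the interferon gene Ifit3 had a log2 ratio of -1.76 against -6.24 in control, a difference of 4.48, Irf7 differed by 3.61, Cebpa by -1.29 and Hp by -3.45. The interferon list differed by a median of 2.92 (percentile 100, 26 of 26 higher), the adipocyte list by -1.07 (percentile 0, 10 of 19 lower, and -1.08 with members at 0 counts set to their bound), cell cycle genes by -0.81 (percentile 0, 9 of 35 lower) and Wnt genes by 0.43 (percentile 100, 5 higher, 2 lower of 22). The cell cycle list started higher in shMaf1 and was above control on both days. Top2a, for example, stood at 200 against 79.4 CPM in control at day 0 and at 686 against 682 CPM at day 2. Some members of the adipocyte list near 0 at day 0 had a larger fold in shMaf1 when no pseudocount was added, with intervals that overlap: Fabp4 was 42.9-fold (19.4 to 118) higher in shMaf1 against 25.1-fold (20.8 to 30.6) in control, Adipoq 82.7-fold (31.9 to 305) against 25.3-fold (17.2 to 38.7) and Cidec 128-fold (22.5 to 5085) against 52.9-fold (32.8 to 91.2), while among members at 5 CPM or more the median difference was -0.948. Glucocorticoid receptor targets differed by -0.27 (percentile 0.53, 1 higher, 4 lower of 18), which was 0.07 under spike-in scaling. Untailed histones differed by -0.52 (percentile 1.04, 1 of 5 lower). A total of 437 genes had a response more positive by the size rule and 310 more negative, against 906 and 168 under spike-in scaling, which shifted the median difference of all genes to 0.29.

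In shBrf1, the response of Fabp4 exceeded that of control by 2.99, that of Cidec by 2.98 and that of Pparg by 0.91, and the response of Dlk1 differed by -1.47. In ML-60218, Fabp4 differed by 2.28, Retn by 2.55, Ogn by -3.17 and Dlk1 by -0.52. The adipocyte list differed by 1.43 in shBrf1 (percentile 100, 13 of 19 higher) and by 1.32 in ML-60218 (percentile 100, 11 higher, 1 lower). The interferon list differed by -0.72 and -0.93 (percentile 0 in both, 9 and 11 of 26 lower), and fibroblast matrix genes by -0.72 and -0.29 (percentile 0 in both). Ribosome biogenesis genes differed by 0.50 in shBrf1 and 0.23 in ML-60218 (percentiles 100 and 99.88), which were -0.05 and -0.39 under spike-in scaling. The 3 macrophage markers differed by -1.52 in shBrf1 (percentile 0.04, 2 lower). That median is the value of Lyz2, of the neighbouring genes on chromosome 10. Lyz2 stood at 23.4 against 7.01 CPM in control at day 0 and at 0.694 against 0.573 CPM at day 2. Cd14 differed by -1.56 and Cd68 by -0.23. The counts were 323 more positive and 622 more negative in shBrf1, and 232 and 324 in ML-60218. Under spike-in scaling they were 120 and 2289, and 77 and 1699, with shifts of the median difference of -0.54 and -0.60.

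The likeness of the 3 perturbations addressed whether Brf1 knockdown and ML-60218 gave responses alike, and opposite to Maf1 knockdown. RNA polymerase III activity was not measured. Of its products, Rmrp and Rpph1 were 152-fold and 97.4-fold higher in shBrf1 at day 2. With ML-60218 at day 2 they stood at 0.114 against 0.202 CPM and 0.153 against 0.169 CPM in control, on few counts. At day 2, Fabp4, Cidec and Cebpa were higher in both shBrf1 and ML-60218 and lower in shMaf1, and Wnt6 and Dlk1 were lower in both and higher in shMaf1. Across 12137 genes, the log2 ratios against control at day 2 correlated with r = 0.64 between shBrf1 and ML-60218, -0.30 between shMaf1 and shBrf1 and -0.31 between shMaf1 and ML-60218. The covariances were 0.169, -0.105 and -0.084, against 0.006 from the counting noise of a shared control in simulated unchanged libraries. The 3′ bias scores at day 2 had the same order, at 0.36 in shBrf1, 0.22 in ML-60218, 0.15 in control and 0.08 in shMaf1. Spearman correlations of the log2 ratio with transcript length were -0.224, -0.163 and 0.113 in shBrf1, ML-60218 and shMaf1. No r was counted as moved or reversed with the length trend removed. Library quality acting by another route was not tested and may add to these correlations. The lists of genes past the size rule share 1 control library, and whatever sets that library apart adds to overlap in the same direction, so the numbers for independent lists that follow are no strict reference. Genes higher in both shBrf1 and ML-60218 numbered 91 (5.27 for independent lists), genes lower in both 202 (20.9), and genes in opposite directions 0 (10.3) and 2 (10.7). Those 2, Eno2 and Ptprn, lower in shBrf1 and higher in ML-60218, were named after their values were seen. Of genes higher in shMaf1, 142 were lower in shBrf1 (22.4) and 123 lower in ML-60218 (12.6). Of genes lower in shMaf1, 77 were higher in shBrf1 (10.7) and 54 higher in ML-60218 (6.06). In the same direction, shMaf1 and shBrf1 shared 11 higher (10.1) and 28 lower genes (23.7), and shMaf1 and ML-60218 10 higher (5.73) and 28 lower genes (13.4). At day 0, r was 0.02 between shMaf1 and shBrf1, 0.11 between shMaf1 and ML-60218 and 0.34 between shBrf1 and ML-60218, with covariances of 0.002, 0.007 and 0.016 against 0.005 in each simulation, and the first r was -0.02 among genes at a mean of 10 CPM or more. In the simulations r itself was 0.49 for each pair at day 0, as only counting noise and the shared control entered. The covariances, and not r, were therefore set against them. Genes are not independent replicates, and these correlations carry no p-value.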

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

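The tests of untailed RNAs and of the neighbouring genes on chromosome 10 were chosen only after the result was seen, while the tests of transcript length and of progress on the adipocyte genes were set down before their results were seen, that of transcript length after the quality tables had been seen.

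Gene lists whose median lay on opposite sides of 0 at the 2 days drew attention. The difference between days equals the difference of responses and was ranked among random lists, but it was not tested against replicates, since each day had 1 library per group. Ribosome biogenesis genes in shBrf1 against control stood at -0.081 at day 0 and 0.38 at day 2 (median difference 0.50, percentile 100), and under spike-in scaling the day 2 median was -0.30 and the difference -0.05. Endoplasmic reticulum chaperones with ML-60218 stood at -0.12 and 0.38 (difference 0.50, percentile 100), with -0.23 at day 2 and a difference of -0.12 under spike-in scaling. Interferon response genes in shMaf1 stood at -0.57 and 2.21 (difference 2.92, percentile 100). At day 0 this list was lower than the shared control in shBrf1 and ML-60218 too. Fibroblast matrix genes in shBrf1 stood at 0.16 and -0.47 (difference -0.72, percentile 0). Quality measures outside the gene counts that lay above 1.2 times the higher control library were 7.8% ribosomal RNA reads in shBrf1 at day 2 (control at most 0.89%), 3′ bias scores of 0.36 in shBrf1 and 0.22 in ML-60218 at day 2 (control at most 0.15), ratios of reads in 3′ to 5′ untranslated regions of 9.557 and 7.882 in the same libraries (control at most 6.09), ERCC reads of 8.14 and 7.76 per 1000 aligned reads in the same libraries (control at most 5.46), and 33.35% of reads sharing their first 35 bases in shBrf1 at day 2 (control at most 26.55%), which were not tested.

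RNAs that lack poly(A) tails were higher in the shBrf1 day 2 library, among them Rn45s, at 44891 against 1781 CPM in control, and the RNA polymerase III products Rmrp, at 30.8 against 0.202 CPM, and Rpph1, at 16.4 against 0.169 CPM. An increase limited to RNA polymerase III products is argued against by the log2 ratio of 4.66 for Rn45s, which RNA polymerase I transcribes. Carry-over of untailed RNA into this library predicts that small nucleolar RNAs of other origin are higher there. Of 13 such genes with 10 or more counts over the other 7 libraries, 10 were highest in it, against 1.62 if every library were equally likely. Only 4 had a counting interval above 1-fold against control at day 2, and of the 2 most abundant Snord88a was 1.69-fold higher (1.38 to 2.06) and Snord96a was at 0.75 of control (0.63 to 0.89). The ranks go with more small nucleolar RNA in this library, but with few counts for most of these genes carry-over is not settled. The untailed histone list, whose members were not shown to lack tails, had a median of 0.91 in this library but also 0.72 in shBrf1 at day 0, where Rn45s stood at 1016 against 799 CPM. What the Rmrp and Rpph1 values say about RNA polymerase III activity stays open, as does a biological increase of untailed RNAs in shBrf1, since the library is the only one of its group.

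Adipocyte genes were higher in the day 2 libraries of shBrf1 and ML-60218, which also had more 3′ bias, and lower in shMaf1, which had less. Across the 4 day 2 libraries the bias score (0.08 in shMaf1, 0.15 in control, 0.22 in ML-60218, 0.36 in shBrf1) had the same order as the adipocyte medians. The fitted trend on transcript length in shBrf1 at day 2 ran only from -0.82 to 0.62. Its removal could therefore not have undone the adipocyte median of 2.19, which was 2.12 afterwards. A length trend of the fitted size is too small to account for that median, and the removal tests nothing beyond this. Untailed histones moved the same way in shMaf1 (-0.66) and shBrf1 (0.91) and were not apart in ML-60218 (-0.10), and a difference in RNA selection, or bias by a route other than length, was not tested for the adipocyte genes and stays open. Progress along the day 0 to day 2 response was judged from a library pair outside each comparison. Less progress may account for part of the pattern in shMaf1 (r = -0.55 with the ML-60218 response, across 12137 genes). Against the shMaf1 response, r was 0.14 for ML-60218, where further progress may account for part, and 0.075 for shBrf1, near 0. These values lie close together and do not set the conditions apart. The shMaf1 response may be a weak guide to progress, since interferon genes were not apart in it. Whether those genes mark progress was not tested, and the adipocyte, glucocorticoid receptor, cholesterol and cell cycle lists were apart in that response. Further progress stays open for shBrf1, whose correlation with the ML-60218 response was not computed. Genes are not independent replicates, so these r values carry no p-value. Culture differences such as confluence at induction stay open, as does an effect of RNA polymerase III activity itself, since each condition was grown once.

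Neighbouring genes on chromosome 10 (mm10, 116905784 to 118168999, 14 genes from Rab3ip to Mdm1) mostly differed from control in 1 direction in each knockdown, with medians of -0.63 and -0.65 in shMaf1 at day 0 and day 2 (10 and 11 of 14 below 0) and 0.70 and 0.68 in shBrf1 (12 of 14 above 0 on both days), against -0.005 and 0.003 in ML-60218. Of 11835 windows of 14 neighbouring genes, 2 and 66 had a median as far from 0 in shMaf1 and 2 and 44 in shBrf1. The 10 genes on either side had medians between -0.13 and 0.10. The borders and length of the block were set after these ratios had been seen. Its rank among windows and the medians beside it follow in part from that choice and are no test. The fitted trend on transcript length in shBrf1 at day 0 ran only from -0.15 to 0.15. Its removal could therefore not have undone the block median, which stayed at 0.70. A length trend of that size is too small to account for the block, and bias by another route was not tested. A copy number change that covers every gene of the block alike is argued against by the mean log2 ratio of -0.39 of Mdm2 and Slc35e3 inside it in shBrf1 at day 0. These genes went against the block in shMaf1 as well (0.05 and 0.30 at day 0). A candidate explanation that stays open is a copy number difference between sublines over part of the block, since DNA was not measured, and a local effect on transcription was not tested.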

How the results depend on the processing

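The length-trend alternative was chosen after seeing the data, and no library could be left out, since each group had 1. The counts of genes past the size rule, in each direction of the 13 comparisons, stayed within 1.5 times their value in 26 of 26 cases with DESeq2 size factors and in 26 of 26 with the length trend removed. Over all alternatives 175 counts did so and 45 moved further. With all expressed genes as background, members at 5 CPM or more, a pseudocount of 1 or the length trend removed, 1485 list medians kept their side of the percentile limits, 44 passed a limit that they had not reached, 56 no longer reached it and 1 was counted as reversed. Of 226 list medians that were apart, 55 changed sign under ERCC scaling, and 0 with DESeq2 size factors or library totals. Among lists given as apart, those no longer apart with the length trend removed were, in shBrf1 at day 2, preadipocyte markers, Wnt genes, tRNA synthetases and endoplasmic reticulum chaperones, ribosomal proteins in shBrf1 at day 0, Wnt genes and ribosomal proteins with ML-60218 at day 2, and, in day 2 against day 0, oxidative phosphorylation genes in shMaf1 and bone genes in control. With members at 5 CPM or more they were preadipocyte markers in shBrf1 at day 2, Wnt and basement membrane genes with ML-60218 at day 2, ribosomal proteins in shBrf1 at day 0, chaperones in shMaf1 at day 0, bone genes in shMaf1 at day 2 and, in day 2 against day 0 of control, preadipocyte markers, NF-kB genes and bone genes. With all expressed genes as background they were chaperones in shMaf1 at day 0 and tRNA synthetases in shBrf1 at day 2. Of named gene values, 6776 kept their side of the size rule, 123 came past it, 172 no longer passed it and 5 were counted as reversed. The 6776 include values short of the size rule that changed sign, such as Pparg with ML-60218 at day 2 under spike-in scaling. Depth limits genes below about 1 CPM, where intervals span several fold. The cause was not tested for the values that follow, except that a scaling factor shifts every gene of a library alike.

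Under ERCC scaling, the numbers higher and lower were 94 and 3016 in shBrf1 and 64 and 1495 in ML-60218 against control at day 2, and 11 and 16 in ML-60218 at day 0, while the number lower at day 0 was 267 in shMaf1 and 133 in shBrf1. For day 2 against day 0 they were 474 and 3609 in control, 351 and 1377 in shMaf1, 386 and 7283 in shBrf1 and 326 and 7759 in ML-60218. For the difference of responses they were 906 and 168 in shMaf1, 120 and 2289 in shBrf1 and 77 and 1699 in ML-60218. In day 2 against day 0 with ML-60218, Rpl8 (-0.091), Rpsa (-0.29), Ebf2 (-0.12) and Etfb (-0.005) were among the named genes that reversed under this scaling. With library totals, 999 genes were higher in day 2 against day 0 with ML-60218.

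With a floor of 5 CPM, 83 genes were lower in shMaf1 at day 0, 30 higher in shBrf1 at day 0, 2 higher and 3 lower in ML-60218 at day 0, 238 lower in ML-60218 at day 2, 451 lower in day 2 against day 0 of shMaf1, and 149 had a more positive response in ML-60218. Without a floor, 10 were higher in ML-60218 at day 0. With a pseudocount of 1, 37 were higher in shBrf1 at day 0, 2 higher and 4 lower in ML-60218 at day 0, and 212 had a more negative response in ML-60218. With a pseudocount of 0.1, 93 were higher and 117 lower in shBrf1 at day 0, 15 and 30 in ML-60218 at day 0, and 548 had a more negative response in ML-60218. By the authors' log2 fold change, 214 were lower in shMaf1 at day 0, 100 higher and 134 lower in shBrf1 at day 0, and 21 and 41 in ML-60218 at day 0. With members at 5 CPM or more, immediate early genes in day 2 against day 0 of control reversed to 0.10. Among genes at a mean of 10 CPM or more, the likeness of shMaf1 and shBrf1 at day 0 reversed to r = -0.015, that of shMaf1 and ML-60218 was 0.071, and at day 2 r was -0.34 for shMaf1 and shBrf1, -0.40 for shMaf1 and ML-60218 and 0.68 for shBrf1 and ML-60218. Spearman's coefficient was 0.30 for shBrf1 and ML-60218 at day 0, and -0.28 and -0.27 at day 2 for shMaf1 with shBrf1 and with ML-60218.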

Other observations

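The test of hypoxia-inducible genes was chosen only after the result was seen.

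Genes that respond to low oxygen were higher with ML-60218 at day 2. Of 8 genes that drew attention to this, Bnip3 had a log2 ratio of 2.35 against control, Ak4, an adenylate kinase, 2.4, Egln3, a prolyl hydroxylase that senses oxygen, 2.20, Gbe1, a glycogen branching enzyme, 2.17, and Car9, a carbonic anhydrase, 2.39 from 0.067 CPM in control. A hypothesis is that these cells showed a response shared by hypoxia-inducible genes in general. Among 31 other measured genes of a hypoxia list drawn up after those were seen, the median log2 ratio was 1.28 (percentile 100), with 29 above 0, 19 higher and 1 lower past the size rule. They included Pdk1, which limits pyruvate entry into mitochondria, at 188 against 46.3 CPM, Pgk1 at 1886 against 590 CPM and Ldha at 2148 against 792 CPM, both of glycolysis, and Egln1 at 112 against 35.2 CPM. Vegfa, a growth factor of blood vessels, had a log2 ratio of 0.06, and Lox, which encodes a collagen crosslinking enzyme, was the member that was lower, at -1.21.

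The same 31 genes had medians above those of matched lists in shBrf1 at day 0, at 0.23 (percentile 100, 24 above 0), and with ML-60218 at day 0, at 0.05 (percentile 98.73, 20 above 0), with 0 past the size rule in both, and a median below them in shMaf1 at day 2, at -0.25 (percentile 0.18, 8 above 0, 2 higher and 2 lower past the size rule). They were not apart in shMaf1 at day 0, at -0.06 (percentile 10.87), or in shBrf1 at day 2, at 0.01 (percentile 52.06, 16 above 0). In day 2 against day 0 the median was 1.60 with ML-60218 and 0.34 in control. A shared response to low oxygen, or to another activator of the same genes, may underlie the median of 1.28, and nothing in the tables tells these apart.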
